A study of Mus musculus with 7 samples.

How the data were processed

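The series holds 10x Chromium 3′ single-cell RNA libraries of mouse spleen T cells in 7 libraries and 5 groups: naive DNT (2 libraries), activated DNT (2), CD4 (1), CD8 (1) and TCRab (1). The matrices deposited by the authors hold raw UMI counts per gene and cell barcode, in the unit counts, without normalization. The labels name Cell Ranger 2.1.0 and 3.0.1 with the mm10 (GRCm38) build for the series. The headers of the kit v3 matrices name software version 3.0.2, and those of kit v2 none. The 5 kit v2 libraries use a reference of 27998 genes and the 2 kit v3 libraries one of 31053 genes. Comparisons used the 27514 gene IDs in both, so 3539 genes of the v3 and 484 genes of the v2 reference were left out, among them all T cell receptor constant genes, Trdc, the Tcrg genes, Igkc and Ighm, which the v2 reference lacks. Depth is the total UMI count per library, given in the report, and UMIs outside the shared genes were 0.400% to 0.594% of each total.

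Barcodes with at least 200 genes and at most 10% mitochondrial UMIs were kept: 4294 of 4334 in TCRab, 4049 of 4072 and 6728 of 7248 in naive DNT, 1791 of 1808 and 1549 of 1634 in activated DNT, 5035 of 5069 in CD4 and 4655 of 4670 in CD8. Scrublet in scanpy 1.11.5 called 0% to 0.581% of cells doublets, which is too few to be informative, so no cell was left out for it in the values reported. Analysis used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Gene coordinates are from GENCODE vM21 on GRCm38, in which 153 of 153 IDs of named genes matched.

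For activated against naive DNT cells, UMIs were summed per library, filtered with filterByExpr, scaled with TMM and tested with edgeR's robust quasi-likelihood F test, 2 against 2 libraries, with Benjamini-Hochberg adjustment at 0.05. The residual degrees of freedom were 2, the biological coefficient of variation 0.429 and the median log2 fold change −0.05. Replicate numbers match the library kit in both groups, and deviations of same-numbered libraries from their group means correlated across genes with r = 0.617, where genes are not independent replicates. A fit with the number as a block (1 residual degree of freedom, coefficient of variation 0.227) is given beside each call or list count named in the report that it changes. On simulated counts with the unblocked spread the test recovered 104 of 200 spiked genes (0% of 2-fold, 28% of 4-fold, 80% of 8-fold and 100% of 16-fold changes) with 14 false calls. With the spread of the blocked fit the same test recovered 161 of 200 with 15 false calls. Both simulations drew the libraries independently, without the correlation of same-numbered libraries. They therefore do not measure recovery or false calls under that correlation. Lists of 18 gene groups were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, with which 0 of the 12 lists past adjusted p 0.05 stayed past it, and with fry, which tests whether a list's genes move one way. For each list the number of called genes is given over all genes and adjusted over the list alone.

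For naive DNT against CD4, CD8 and TCRab, each with 1 library, no test was made. CPM over shared genes was compared, and a gene counted as different when it was at least 2-fold apart in the same direction against both naive libraries with at least 20 CPM in every library of the higher side. Ratios have exact conditional 95% intervals for counting error only. Where a group had 0 UMIs the fold was computed against a floor of 3 UMIs and is written as at least. List medians used log2 ratios of CPM with 0.5 added and were compared with 10000 random lists of the same size matched on expression in 20 bins. Genes of a random list were drawn independently from the same pair of libraries. The random ranges therefore hold neither correlation between genes of a list nor spread between libraries. On simulated counts with counting error only, the rule called 0% of 1.5-fold and 100% of 3-fold changes, with 0 false calls. The simulation held no spread between libraries or kits, so it does not measure false calls that such spread would cause.

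For clusters, the libraries of each DNT group were scaled to 10000 counts per cell, log-transformed, scaled per library (z scores up to 10), and clustered on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method (10 iterations, resolution 0.6, seed 1). A cluster took a cell type name when at least 3 markers of its list were at least 1.5-fold above the other cells in each library with at least 10 cells (20 CPM added) and at 20 CPM or more there, no other list had as many, and no other list had more members among the cluster's 10 leading genes. A cluster whose median UMIs lay far under its libraries' medians and whose leading genes held no marker stayed unnamed. Cd4 and Cd8 classes were counted after thinning each cell to 1500 UMIs. Shares have exact Clopper-Pearson intervals.

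The groups, comparisons, gene lists, cell type markers, filters, resolution, principal components, neighbours and the rule for named genes were fixed before the data were examined. The neighbour graph (shared neighbours with Jaccard weights), the naming rule and its limits, and the definition of red cell, myeloid and B cell clusters to leave out were chosen after the clusters had been seen. Named genes were, for activated against naive, the 6 highest and 6 lowest fold changes among called genes with a mean log2 CPM of at least 5 and the same direction in both replicate numbers, and up to 4 members of each list by p. For the size comparisons they were the 10 highest and 10 lowest ratios among genes of at least 50 CPM that met the rule, and up to 4 members of each list. A fixed set was always included: Cd4, Cd8a, Cd8b1, Trdc, Tcrg-C1, Klrb1c, Zbtb16, Cd3e, Foxp3, Il2ra, Gzmb, Prf1, Ifng, Lef1, Ccr7, Ikzf2, Fcer1g and 1 gene not reported here, and a cluster name that needs it is left out. Of these, Cd4 and Foxp3 were not tested between activated and naive cells because of low counts. Alternatives covered the normalization, the low-count filter, the test, the barcode filters, thinning, doublets, leaving out each library, the block, the size rule, the clustering settings and the depth of thinning.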

Results

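The data are single-cell RNA sequencing libraries of T cells sorted from the spleens of 8-week-old male C57BL/6 mice, made with 10x Chromium 3′ kits that capture polyadenylated RNA. All sorts took CD3+ NK1.1− TCRαβ+ TCRγδ− cells. Naive double-negative T cells (DNT cells, which carry neither CD4 nor CD8) were also sorted as negative for αGal-CD1d and LPC-CD1d tetramers, which bind NKT cells, and gave 2 libraries. Activated DNT cells were naive DNT cells cultured for 3 days with antibodies to CD3 and CD28 and 20 ng/ml IL-2, and also gave 2 libraries. CD4 T cells, CD8 T cells and the parent TCRαβ+ gate (TCRab) gave 1 library each. Replicate 1 of each DNT group and the 3 unreplicated groups were made with kit v2, and replicate 2 of each DNT group with kit v3. The 7 libraries held 28101 cells after filtering. Total UMI counts in these cells were 17358231 and 53653855 for naive DNT replicates 1 and 2, 34521240 and 25347948 for activated DNT replicates 1 and 2, 21757994 for CD4, 24115584 for CD8 and 18373324 for TCRab. Median UMIs per cell were 4119 and 7556 in the naive DNT libraries, 15795 and 9386 in the activated DNT libraries, 4087 in CD4, 4899 in CD8 and 3987 in TCRab.

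The comparison of activated with naive DNT cells addresses how these cells differ after culture with stimulation through the T cell receptor and CD28 and with IL-2. No group was cultured without stimulation. Effects of stimulation therefore cannot be told apart from those of the 3 days of culture, for rises and falls alike. The activated libraries held transcripts of Ccl20, Ccl1 and Il13, which were near or at 0 counts in the naive libraries. They also held more of Il2ra, Gzmb and cell cycle genes. Ccl20 and Il13 were among the leading genes of an unnamed cluster with 10.1% of activated replicate 1 and 1.48% of activated replicate 2. Gzmb (granzyme B, ENSMUSG00000015437, chromosome 14, 56258838 to 56262260 in GRCm38) rose from 16.1 ± 3.47 to 2553 ± 228 TMM-scaled CPM (mean ± SD, n = 2 and 2), which is 158-fold. Other transcripts were lower in the activated libraries, among them Dapl1 (a gene of resting T cells, ENSMUSG00000026989, chromosome 2, 59484653 to 59505020), from 58.1 ± 29.6 to 2.76 ± 2.103 CPM, and Fosb (an AP-1 subunit, ENSMUSG00000003545, chromosome 7, 19302696 to 19310051), from 270 ± 126 to 1.19 ± 0.325 CPM. UMIs were summed over the cells of each library. A change within cells therefore cannot be told apart from a changed mix of cells. Of 12325 genes tested, 656 were higher and 624 lower in activated cells (edgeR quasi-likelihood F test, Benjamini-Hochberg adjusted p under 0.05), all of them by at least 2-fold. Below, values are mean ± SD of TMM-scaled CPM over the 2 libraries of each group or log2 fold changes ± SE, and each change named passed this test unless it is said not to.

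Among the genes with the largest increases was Ccl20 (a chemokine that attracts CCR6+ cells, ENSMUSG00000026166, chromosome 1, 83116766 to 83119167). It had 0 UMIs in both naive libraries and 251 ± 169 CPM in the activated ones, at least 6269-fold higher with 3 UMIs over the naive group as the floor. Ccl1 (a CCR8 ligand, ENSMUSG00000020702, chromosome 11, 82176657 to 82305690) had 2 UMIs in the naive group and 1154 ± 985 CPM in the activated one, a pooled ratio of 43213 with a 95% counting interval of 11962 to 356833. Il13 (a type 2 cytokine, ENSMUSG00000020383, chromosome 11, 53631324 to 53634702) rose by 9.78 ± 0.99 on the log2 scale. Asns (asparagine synthetase) rose by 8.05 ± 0.51 and Serpine2 (a protease inhibitor) by 7.53 ± 0.65. The largest decreases among genes with at least a mean log2 CPM of 5 were in the red cell genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt, followed by Fosb (−7.83 ± 0.67) and Dtx1 (a regulator of Notch signalling, −6.33 ± 0.53). Hba-a1 had 0 UMIs in the activated libraries and was at least 7170-fold lower than in the naive ones, and Hba-a2, a near-identical copy, at least 5537-fold lower. Hbb-bs had 2 UMIs in the activated libraries, a pooled ratio of 19712 with a counting interval of 5456 to 162771, and Hbb-bt changed by −10.78 ± 1.54. With cells of the clusters led by red cell, myeloid and B cell genes left out (71 of 4049 and 164 of 6728 naive cells, and 0 of 1791 and 0 of 1549 activated cells), the spread grew and these 4 calls ended, while the differences stayed large. Hba-a1 was then at 96.2 and 3.63 CPM in the naive libraries, at least 415-fold higher than in the activated ones (log2 SE 4.30 after and 2.29 before, edgeR adjusted p 0.244), and Hba-a2 was at least 329-fold higher (4.45 and 2.39, adjusted p 0.264). The pooled ratio of Hbb-bs was 1573 (435 to 12990, SE 2.49 and 1.70, adjusted p 0.0721) and that of Hbb-bt 48.5 (25.4 to 107, SE 2.07 and 1.54, adjusted p 0.142).

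**Figure D1:**
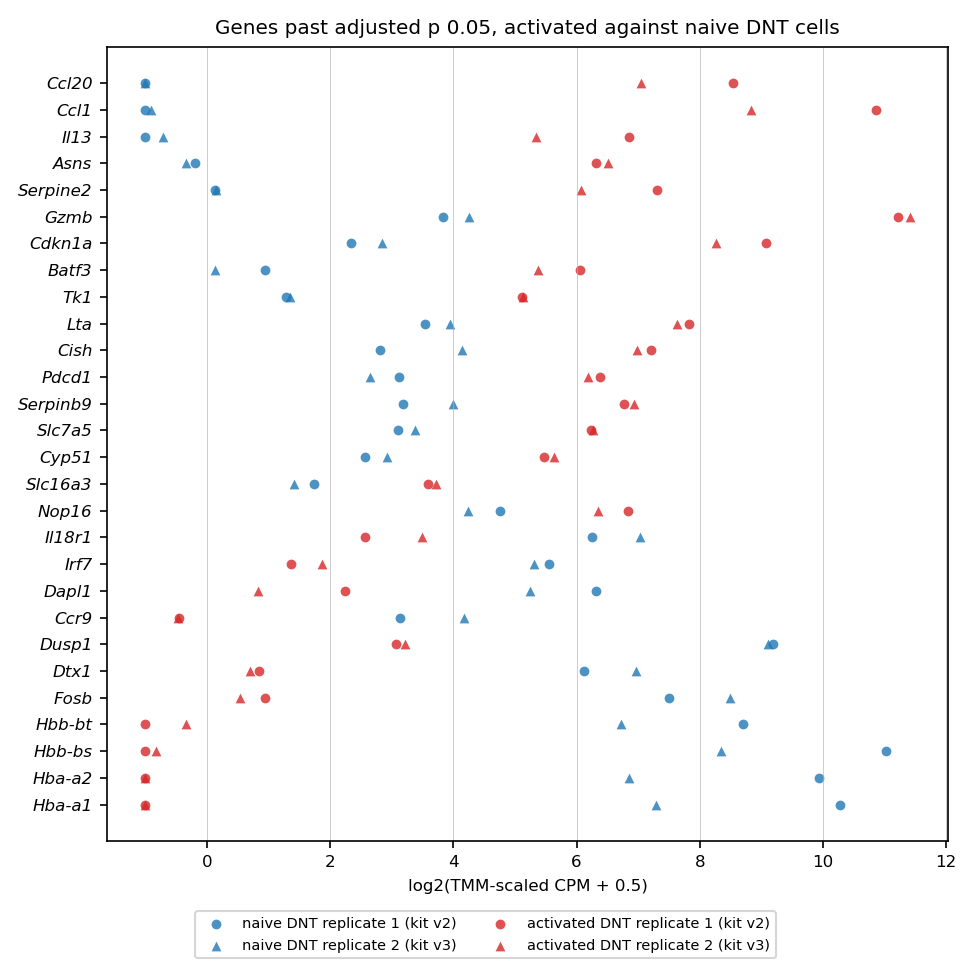
TMM-scaled CPM on a log2 scale, with 0.5 added, of 28 genes past adjusted p 0.05 in naive (blue) and activated (red) DNT libraries. Each point is 1 library, with circles for replicate 1 (kit v2) and triangles for replicate 2 (kit v3). Gzmb lies at 16.1 ± 3.47 CPM in naive and 2553 ± 228 CPM in activated cells, and the red cell genes at the bottom have 0 to a few UMIs in activated cells.

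Of 26 proliferation genes, 19 rose and 0 fell, and 24 rose when adjusted over the list alone and 25 with the replicate number as a block. Tk1 (thymidine kinase) rose by 4.10 ± 0.40, Ccna2 (cyclin A2) by 4.34 ± 0.44, Cdk1 by 4.17 ± 0.43 and Aurkb by 4.17 ± 0.44. Camera gave the proliferation list an adjusted p of 6.51e-16, and adjusted p = 0.295 with an estimated correlation. Of 15 apoptosis regulators, 4 rose and 0 fell, and 4 rose when adjusted over the list alone (8 rose with the block). They were Cdkn1a, an inhibitor of the cell cycle (5.60 ± 1.51 to 424 ± 167 CPM), the antiapoptotic genes Bcl2a1d (3.86 ± 0.57) and Bcl2a1b (3.07 ± 0.47), which are near-identical copies, and Ccng1 (2.39 ± 0.46). Bcl2a1b and Ccng1 were not past the threshold without naive replicate 1 (edgeR adjusted p 0.0624 and 0.0893), nor Ccng1 without naive replicate 2 (0.104). For apoptosis regulators camera gave an adjusted p of 0.00642, and adjusted p = 0.327 with an estimated correlation.

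Cytokine and chemokine genes mostly rose. Of 22 tested, 14 rose and 1 fell, and 17 rose and 2 fell when adjusted over the list alone, and 16 rose and 2 fell with the block. Ccl4, which encodes a chemokine, rose from 44.4 ± 21.6 to 4410 ± 1642 CPM and Lta (lymphotoxin alpha) from 13.0 ± 2.66 to 212 ± 19.8 CPM. Ccl5 moved the other way, from 10290 ± 6779 to 422 ± 30.6 CPM. Ifng rose from 68.5 ± 11.1 to 523 ± 61.9 CPM (log2 2.93 ± 0.49, edgeR adjusted p 0.0159), with adjusted p 0.0827 without naive replicate 1 and 0.0758 with cells thinned to 1500 UMIs. The cytokine list had a camera adjusted p of 1.38e-09, and adjusted p = 0.295 with an estimated correlation. Of 14 cytotoxic effector genes, 4 rose and 1 fell (4 and 2 adjusted over the list alone, 6 and 2 with the block). Beside Gzmb, Serpinb9, an inhibitor of granzyme B, rose by 3.25 ± 0.46 and Gzmc by 3.67 ± 0.60, and Gzmm (granzyme M) changed by −2.99 ± 0.52 (adjusted p 0.0178, and 0.0764 without naive replicate 1). Prf1 (perforin) did not pass the test (log2 0.54 ± 2.06, adjusted p 0.902), with 2.67 and 28.0 CPM in the naive libraries and 1.19 and 43.8 CPM in the activated ones. The camera adjusted p of this list was 0.267.

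Receptors of activation and coinhibition split. Of 18 activation and costimulatory receptor genes, 5 rose and 1 fell, 5 rose and 2 fell when adjusted over the list alone, and 8 rose and 5 fell with the replicate block. Il2ra (the IL-2 receptor alpha chain) rose from 8.0 ± 6.48 to 196 ± 38.9 CPM, Tnfrsf9 (the 4-1BB receptor) from 18.0 ± 8.57 to 656 ± 239 CPM and Slc7a5 (an amino acid transporter) from 8.99 ± 1.26 to 75.6 ± 0.668 CPM. The camera adjusted p was 0.0812 for the list and 0.0191 without activated replicate 2. Of 13 coinhibitory receptor genes, 2 rose and 2 fell, 4 rose and 2 fell when adjusted over the list alone, and 4 rose and 3 fell with the block, with a camera adjusted p of 0.595 and 0.0395 by fry. Pdcd1 (PD-1) rose from 6.97 ± 1.70 to 77.5 ± 6.87 CPM and Havcr2 (TIM-3) from 0.374 ± 0.108 to 7.58 ± 0.837 CPM. Cd244 fell by 2.55 on the log2 scale (SE 0.49, adjusted p 0.0239, and 0.110 without naive replicate 1). Of 18 STAT5 and NF-kB target genes, 4 rose and 2 fell (5 and 2 adjusted over the list alone, 9 and 3 with the block), with a camera adjusted p of 0.241. Cish, a STAT5 target, rose by 3.52 ± 0.56, and Tnfaip3, which encodes the NF-kB inhibitor A20, changed by −4.22 ± 0.74.

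Lineage transcription factor genes also split, with 3 of 24 higher and 3 lower (4 and 3 adjusted over the list alone, 3 and 7 with the block). Batf3 rose by 5.82 ± 0.62 and Irf8 by 3.51 ± 0.53. Ikzf2 (Helios, ENSMUSG00000025997, chromosome 1, 69531214 to 69687245) changed by −1.92 ± 0.46 (adjusted p 0.0410), and its adjusted p lay between 0.0929 and 0.245 with any 1 of the 4 libraries left out. The list's camera adjusted p was 0.598, and its median and test pointed down where its mean was 0.17. Zbtb16 (PLZF) was at 12.8 ± 11.2 CPM in naive and 10.7 ± 3.68 CPM in activated cells (adjusted p 0.841).

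Of 20 genes of quiescence and lymphoid homing, 0 rose and 9 fell, 12 fell when adjusted over the list alone, and 1 rose and 15 fell with the replicate block. Dapl1 changed by −4.39 ± 0.74 and Klf3 by −2.38 ± 0.43 (adjusted p 0.0196, and 0.0580 without activated replicate 1). Lef1, a transcription factor of resting T cells, changed by −2.23 ± 0.41 (adjusted p 0.0203, and 0.0674 and 0.0661 without naive replicate 1 and activated replicate 1). Ccr7 did not pass the test (111 ± 29.3 and 123 ± 59.7 CPM, adjusted p 0.886). The list's camera adjusted p was 1.56e-06, and adjusted p = 0.327 with an estimated correlation. Of 16 chemokine receptor and integrin genes, 1 rose and 6 fell, 1 rose and 9 fell when adjusted over the list alone, and 1 rose and 12 fell with the block. Ccr9 (a gut-homing receptor) changed by −5.81 ± 0.61, Ccr2 by −3.30 ± 0.47 and Itgb7 by −3.51 ± 0.51, and Ccr4 rose by 3.11 ± 0.49. This list had a camera adjusted p of 0.000751, adjusted p = 0.327 with an estimated correlation and 0.0658 by fry.

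Of 18 NK and innate-like receptor genes, 0 rose and 7 fell, 12 fell when adjusted over the list alone, and 1 rose and 11 fell with the block. Il18r1 (an IL-18 receptor chain) changed by −3.68 ± 0.54 and Tyrobp, an adaptor of activating receptors that myeloid cells also express, by −4.01 ± 0.71. Cd7 changed by −3.83 ± 0.73 (adjusted p 0.0233, and 0.0953 with the block). Klrb1c, which encodes NK1.1, the marker the sort excluded, was at 14.1 ± 4.51 CPM in naive and 1.60 ± 1.61 CPM in activated cells (adjusted p 0.0655, and 0.0644 with the block), and Fcer1g at 320 ± 194 and 172 ± 20.8 CPM (adjusted p 0.344). The NK list had a camera adjusted p of 4.30e-05, adjusted p = 0.327 with an estimated correlation and 0.0658 by fry. Of 17 interferon response genes, 0 rose and 9 fell (10 when adjusted over the list alone, 13 with the block). Irf7 changed by −4.04 ± 0.44, Ifit3 by −3.99 ± 0.58 and Isg15 by −2.56 ± 0.41. The camera adjusted p was 2.27e-06, and adjusted p = 0.295 with an estimated correlation. Of 16 immediate early and stress genes, 0 rose and 7 fell, 1 rose and 8 fell when adjusted over the list alone, and 1 rose and 10 fell with the block. Beside Fosb, Dusp1 went from 567 ± 20.5 to 8.32 ± 0.682 CPM, Fos from 652 ± 276 to 8.37 ± 4.01 CPM and Zfp36 from 385 ± 136 to 24.6 ± 9.74 CPM. The camera adjusted p was 0.000193, and adjusted p = 0.327 with an estimated correlation. At the clustering settings used, the red cell, myeloid and B cell clusters held 1.75% and 2.44% of cells in the naive libraries and none in the activated ones, and the named genes of these 3 lists kept their calls when those cells were left out. With 15 principal components a B cell cluster held 1 cell of activated replicate 1 and 86 cells (5.55%) of activated replicate 2. In the whole library of activated replicate 2, 18 of 1549 cells had a Cd79a UMI.

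Of 20 genes of the nucleolus and MYC programme, 3 rose and 0 fell, 15 rose when adjusted over the list alone and 19 with the block. Nop16, Nolc1 and Srm (spermidine synthase) rose by 2.12 ± 0.42, 1.90 ± 0.41 and 2.64 ± 0.61, and none of the 3 was past the threshold without naive replicate 1 (adjusted p 0.0784, 0.173 and 0.0989) or without naive replicate 2 (0.127, 0.127 and 0.141), nor Nolc1 and Srm without activated replicate 1 (0.0594 and 0.0503). The list's camera adjusted p was 1.85e-07, and adjusted p = 0.318 with an estimated correlation. Of 16 cholesterol and lipid synthesis genes, 3 rose and 0 fell (4 adjusted over the list alone, 7 with the block). Cyp51 rose by 2.89 ± 0.40, Sqle by 2.58 ± 0.41 and Idi1 by 2.62 ± 0.39, the last with adjusted p 0.0572 without naive replicate 1. The camera adjusted p was 0.00564, 0.0762 without naive replicate 1, adjusted p = 0.407 with an estimated correlation and 0.0935 by fry. Of 16 glycolysis genes, 1 rose (Slc16a3, a lactate exporter, 2.28 ± 0.42, with adjusted p 0.0539 and 0.0767 without naive replicates 1 and 2), 1 when adjusted over the list alone and 9 with the block. Tpi1 was not past the test (1.79 ± 0.48, adjusted p 0.0589, and 0.000184 with the block). The camera adjusted p was 0.00372, and adjusted p = 0.318 with an estimated correlation. Of 20 genes of mitochondrial respiration, edgeR called 0 in either direction, 0 adjusted over the list alone and 10 as higher with the block. Their camera adjusted p was 0.0164, adjusted p = 0.689 with an estimated correlation and 0.446 by fry. Of 20 cytosolic ribosomal protein genes, 0 passed in either direction or adjusted over the list alone, and 1 rose and 3 fell with the block, with a camera adjusted p of 0.595 that lay between 0.0442 and 0.319 with 1 library left out.

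The number of called genes depended on the libraries and on the model. It was 547 without naive replicate 1, 773 without naive replicate 2, 1190 without activated replicate 1 and 2074 without activated replicate 2, and with the replicate number (the library kit) as a block it was 4894, which held 1273 of the 1280 genes. With cells thinned to 1500 UMIs the adjusted p was 0.0560 for Idi1, 0.0595 for Ccr4, 0.0751 for Lef1, 0.0803 for Cd7, 0.0884 for Nop16, 0.0971 for Gzmm, 0.132 for Sqle, 0.137 for Srm, 0.138 for Nolc1, 0.149 for Slc16a3, 0.186 for Klf3 and 0.1996 for Ikzf2. With no filter on low counts that of Hba-a2 was 0.0894.

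The comparison of naive DNT with CD4 T cells addresses how DNT cells differ from conventional T cells. With 1 CD4 library there is no test, so genes are described by size, as at least 2-fold in the same direction against both naive DNT libraries with at least 20 CPM on the higher side. By this rule naive DNT cells carried more transcripts of NK receptors, of Ccl5 and of immediate early genes, and fewer of Cd4, Pdlim4 and Igfbp4. Klra7 (an inhibitory receptor of the Ly49 family, whose members are near-identical, ENSMUSG00000067599, chromosome 6, 130218605 to 130233322) was at 188 and 107 CPM in naive replicates 1 and 2 and had 0 UMIs in CD4, which is at least 1361-fold and 774-fold higher. Klrk1 (the receptor NKG2D, ENSMUSG00000030149, chromosome 6, 129610323 to 129623864) was 167-fold higher in replicate 1 (95% counting interval 120 to 242) and 151-fold in replicate 2. Fcer1g (an adaptor of activating receptors, ENSMUSG00000058715, chromosome 1, 171229572 to 171234365) was 31.4-fold higher (27.7 to 35.9) and 18.8-fold in replicate 2.

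In all 218 genes were higher and 53 lower in naive DNT than in CD4 cells, of 4031 genes with enough counts. Ratios below are those of naive replicate 1, made with the same kit as CD4, and their intervals cover counting error in 1 library only. Klra1 was 340-fold higher (145 to 1048) and Klre1 463-fold (158 to 2251, 3 UMIs in CD4). Xcl1 was 130-fold higher (92.7 to 190), Ly6c2 112-fold (100.1 to 125, and 56.0-fold in replicate 2) and Spry2, an inhibitor of receptor signalling with 0 UMIs in CD4, at least 409-fold. Ccl5 reached 11766 and 6407 CPM in the naive libraries and 176 CPM in CD4, 66.8-fold and 36.4-fold higher. Ikzf2 was 9.10-fold higher (8.43 to 9.83), Eomes 18.8-fold (14.7 to 24.3) and Ifng 15.5-fold (12.1 to 20.3, and 29.2-fold in replicate 2). Among lower genes, Cd4 (ENSMUSG00000023274, chromosome 6, 124864692 to 124888221) had 1 UMI in naive replicate 1 and 137 CPM in CD4, 2364-fold lower (424 to 93405). Pdlim4 was 117-fold lower (65.1 to 234, and 248-fold in replicate 2), Igfbp4 40.5-fold, Ly6c1 24.5-fold (41.1-fold in replicate 2) and Zbtb7b, the factor that directs CD4 lineage choice, 5.63-fold (3.32-fold in replicate 2). Lef1 was 2.83-fold lower (2.71 to 2.96). Ccr7, Cd3e, Gzmb, Prf1, Cd8a and Cd8b1 did not meet the rule, and Foxp3 was at 0.232 CPM in naive replicate 1 and 9.92 CPM in CD4, under the level the rule needs.

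As groups, 11 of 18 NK and innate-like receptor genes were higher in naive DNT than in CD4 cells and 0 lower, with a median log2 ratio of 3.87 (the middle 95% of 10000 random lists matched on expression lay between −0.14 and 0.31). These random ranges allow neither for correlated genes nor for spread between libraries, so a median outside them is not a test. For immediate early and stress genes 9 of 16 were higher and the median was 1.74, with Dusp1 15.8-fold, Fosb 14.2-fold (42.0-fold in replicate 2) and Fos 10.7-fold higher. Cytotoxic genes had a median of 1.30 with 4 of 14 higher, among them Nkg7 (19.8-fold) and Gzma (93.1-fold, and 52.1-fold in replicate 2). Lineage factors (0.81), chemokine receptors and integrins (0.78), cytokines (0.76), STAT5 and NF-kB targets (0.43), apoptosis regulators (0.33) and activation receptors (0.29) lay above the random range, and proliferation (−0.73), cholesterol synthesis (−0.41), quiescence (−0.34), interferon response (−0.30) and ribosomal proteins (−0.17) below it. Tnfaip3 was 29.6-fold and 168-fold higher in replicates 1 and 2. Glycolysis (0.15), respiration (−0.02), nucleolus and MYC (0.02) and coinhibitory receptors (0.24) lay inside it. With naive replicate 2 in place of replicate 1 the random ranges lay higher as well, and the quiescence and cholesterol medians (0.47 and 0.65, random lists −0.24 to 0.60 and 0.23 to 1.28) and that of apoptosis lay inside them and respiration below (−0.25).

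Against CD8 T cells, naive DNT cells again carried more NK receptor, Fcer1g and immediate early transcripts, and fewer of Cd8a and Cd8b1. Cd8a (ENSMUSG00000053977, chromosome 6, 71373427 to 71379173) was 499-fold lower (312 to 857) and Cd8b1 85.7-fold lower (75.9 to 97.1), and in replicate 2 they were 1544-fold and 250-fold lower. Fcer1g was 57.5-fold higher (48.9 to 68.2, and 34.5-fold in replicate 2), Ikzf2 18.2-fold (16.4 to 20.1) and Ifng 56.9-fold (36.6 to 93.6, and 107-fold in replicate 2). By the size rule 184 genes were higher and 21 lower, of 3944. Spry2 was 61.8-fold higher, Dusp1 34.9-fold, Klra1 34.2-fold, Klra7 28.8-fold (16.4-fold in replicate 2), Xcl1 10.8-fold and Ccl5 7.57-fold (4.12-fold in replicate 2). Lyz2, a myeloid gene, was 205-fold higher (317 CPM, 63.9 CPM in replicate 2, and 1.54 CPM in CD8), and Tyrobp 30.3-fold. Without the red cell, myeloid and B cell clusters the log2 ratio of Lyz2 went from 7.28 to 3.19, that of Tyrobp from 4.73 to 3.28 and that of Fcer1g from 5.74 to 5.49. Lower genes included Igfbp4 (13.8-fold), Dapl1 (10.9-fold), Ccr9 (9.59-fold, 3.06-fold in replicate 2) and Gzmm (3.90-fold).

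As groups against CD8 cells, immediate early and stress genes had a median log2 ratio of 2.82 (10 of 16 higher, random lists between −0.06 and 0.34) and NK and innate-like receptors one of 2.15 (10 of 18 higher, −0.03 to 0.38). Cytokines (1.19), lineage factors (1.07), coinhibitory receptors (0.95), activation receptors (0.89), chemokine receptors and integrins (0.78), STAT5 and NF-kB targets (0.58), apoptosis regulators (0.53) and cytotoxic genes (0.46) lay above the random range. Il2rb was 4.46-fold, Cd44 4.20-fold and Cd160 6.38-fold higher in naive DNT than in CD8 cells, and the first of these were 8.45-fold and 8.0-fold higher in replicate 2. Proliferation (−0.45), interferon response (−0.34), ribosomal proteins (−0.31), nucleolus and MYC (−0.24), cholesterol synthesis (−0.22) and quiescence (−0.17) lay below it, and glycolysis (0.25) and respiration (0.06) inside it. In replicate 2 the nucleolus, quiescence and cholesterol medians were 0.31, 0.68 and 1.0, and with the apoptosis and cytotoxic lists these lay inside the random ranges, which were higher too, and respiration below (−0.17).

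**Figure D2:**
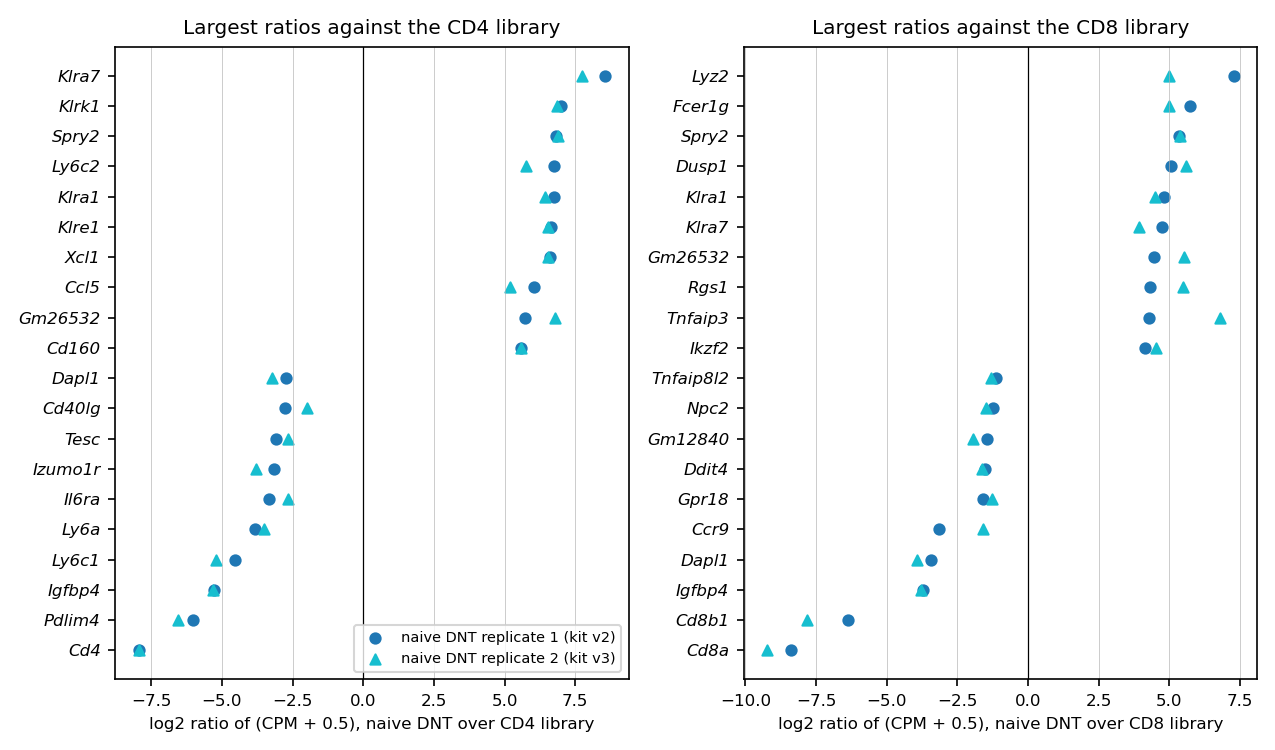
Log2 ratio of CPM, with 0.5 added, of naive DNT cells over the CD4 library (left) and over the CD8 library (right), for the 10 highest and 10 lowest ratios among genes of at least 50 CPM that met the size rule. Circles are naive replicate 1 (kit v2) and triangles replicate 2 (kit v3). Both replicates lie on the same side of 0 for every gene shown, because the size rule requires it. Klra7 is at 8.56 and 7.75 against CD4, and Cd8a is among the lowest against CD8.

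Against the parent TCRab gate, which asks how DNT cells stand apart from all TCRαβ+ cells, 161 genes were higher and 48 lower, of 4082. Spry2 was 148-fold higher (71.4 to 368), Klra1 59.7-fold, Klra7 39.1-fold (22.2-fold in replicate 2), Klrk1 22.4-fold, Ifng 20.6-fold (38.7-fold in replicate 2), Fcer1g 19.9-fold (11.9-fold in replicate 2) and Ccl5 14.1-fold (7.67-fold in replicate 2). Cd4 was 1663-fold lower (298 to 65741), Cd8a 182-fold (113 to 312, and 562-fold in replicate 2) and Pdlim4 83.9-fold (178-fold in replicate 2). The NK list had a median log2 ratio of 2.51 (11 of 18 higher), immediate early genes 1.94 (9 of 16), cytokines 1.11, lineage factors 0.81, cytotoxic genes 0.71, chemokine receptors 0.66, STAT5 and NF-kB targets 0.41, apoptosis 0.31 and activation receptors 0.28, all above the random range. Proliferation (−0.66), interferon response (−0.49), cholesterol synthesis (−0.36), quiescence (−0.34), ribosomal proteins (−0.21) and nucleolus and MYC (−0.19) lay below it, and glycolysis (−0.04), respiration (−0.08) and coinhibitory receptors (0.18) inside it. In replicate 2 the cholesterol, quiescence and nucleolus medians were 0.72, 0.42 and 0.38, inside the higher random ranges of that replicate, as were the apoptosis and activation lists, and respiration lay below it (−0.36).

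Single libraries set the scale of these size comparisons. By the same size measure 96 genes were higher and 1486 lower in naive DNT replicate 1 than in replicate 2, which differ in kit, and 51 higher and 58 lower in CD4 than in CD8. With naive replicate 2 alone 2018, 2101 and 1937 genes differed from CD4, CD8 and TCRab, and with replicate 1 alone 343, 271 and 276. TMM scaling moved all log2 ratios of replicate 1 by −0.16 against CD4, −0.28 against CD8 and −0.10 against TCRab, and those of replicate 2 by −0.68, −0.80 and −0.61, so that every ratio given for replicate 2 depends on the scaling. The replicate 2 medians of quiescence and of the nucleolus list, and that of cholesterol synthesis against CD4, are smaller in size than these shifts. With TMM the size rule gave 259, 171 and 207 genes, of which 154, 111 and 126 were higher in naive DNT. With only list members of at least 20 CPM on the higher side, the proliferation medians against CD4, CD8 and TCRab were −0.06, −0.02 and −0.15 and lay inside the random range, as did apoptosis regulators against all 3 groups, activation receptors and ribosomal proteins against CD4 and cytotoxic genes against CD8.

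Naive DNT cells fell into 16 clusters when both libraries were clustered together. The largest named class, innate-like T cells, held 39.3% (95% exact binomial interval 37.8 to 40.8) of cells in replicate 1 and 39.8% (38.6 to 40.9) in replicate 2. Its 3 clusters were led by Klrc2, Klrk1, Klre1, Klra7 and Xcl1, by Myl1, Klrb1a, Cd7, Fcer1g and Cd160, and by Ccl4, Tnfrsf9 and Xcl1. A type 17-like cluster with Ccr6, Il1r1, Cxcr6, Tmem176a and Tmem176b held 4.40% (3.79 to 5.07) and 12.9% (12.1 to 13.8), a resting-like cluster with Ccr9, Igfbp4, Dapl1 and Lef1 3.73% (3.17 to 4.36) and 3.86% (3.42 to 4.35), and a cluster with Isg15, Ifit3 and Irf7 2.03% (1.61 to 2.51) and 2.39% (2.04 to 2.79). Cytotoxic-like cells with Gzma, Gzmb and Gzmk held 1.58% (1.22 to 2.01) and 0.862% (0.655 to 1.11), and cycling cells 0.222% (0.102 to 0.422) and 0.416% (0.277 to 0.601). Clusters without a name by the rule included the largest single one, led by Actn1, Rgs10 and Dapl1 (32.0% and 26.4%), and one led by Slamf7, Rgs16 and Eomes (13.2% and 6.03%). The names depend on the resolution: at 0.3 instead of 0.6 the innate-like class held a mean of 10.7% of the 2 libraries instead of 39.5%, and the cytotoxic-like class 60.0% instead of 1.22%.

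Activated DNT cells fell into 10 clusters. Cycling cells with Top2a, Birc5 and Mki67 held 14.7% (13.1 to 16.4) of replicate 1 and 9.17% (7.78 to 10.7) of replicate 2, with a median of 27475 and 53391.5 UMIs per cell. A type 17-like cluster with Il17a, Il23r, Maf and Cxcr6 held 5.47% (4.46 to 6.63) and 18.1% (16.3 to 20.2), and a type 1-like cluster led by Nr4a1, Nr4a2 and Egr1 with Ccl3, Ccl4 and Tnf 10.2% (8.85 to 11.7) and 9.55% (8.14 to 11.1). The type 1-like name rests on Ccl3, Ccl4 and Tnf alone, since Ifng, Cxcr3, Tbx21 and Il12rb2 of that list did not reach the naming limits. A cluster led by Klf2, Cd7 and Arl4c held 12.6% (11.1 to 14.2) and 28.9% (26.7 to 31.3). The largest cluster in replicate 1, led by Xcl1, Il4i1 and Gzmb, had no name and held 30.5% and 16.7%. The type 1-like class was found at the resolutions 0.6 and 1.0 but had no cluster at 0.3, and neither had the type 17-like class. Without per-library scaling a type 17-like cluster held 3 of 1791 cells (0.168%) of replicate 1 and 17.8% of replicate 2.

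**Figure D3:**
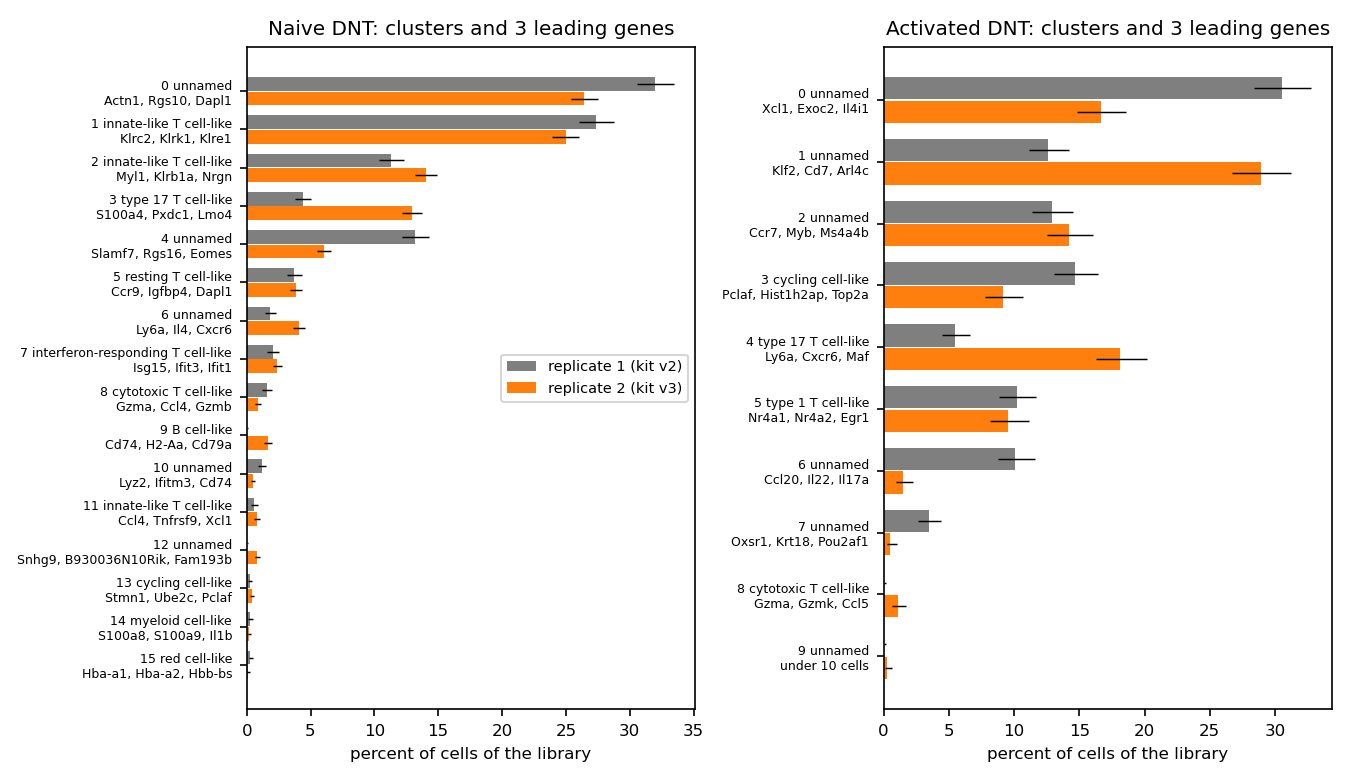
Percent of cells in each cluster of the naive DNT libraries and of the activated DNT libraries. Bars are single libraries with exact 95% binomial intervals, which cover counting error only. The type 17-like cluster holds 4.40% and 12.9% of naive and 5.47% and 18.1% of activated cells in replicates 1 and 2.

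Transcripts of Cd4, Cd8a and Cd8b1 followed the sort gates. After each cell was thinned to 1500 UMIs, 97.45% (96.9 to 97.9) and 99.1% of naive DNT cells and 99.2% and 98.8% of activated DNT cells had a UMI of neither Cd4 nor Cd8. In the CD8 library 90.9% of cells had a Cd8a or Cd8b1 UMI and 0 of 4645 a Cd4 UMI. The exact interval of the latter share allows up to 0.0794% of cells with a Cd4 UMI at this depth. It does not bound the share of cells expressing the gene. In the CD4 library 17.9% had a Cd4 UMI only, 2.94% a Cd8 UMI and 79.2% neither, so at this depth most cells sorted as CD4+ had no Cd4 UMI. The share of cells with a Cd8 UMI was 2.52% (2.06 to 3.06) in naive replicate 1 (median 4119 UMIs before thinning), 0.887% (0.676 to 1.14) in naive replicate 2 (7556 UMIs) and 2.94% (2.49 to 3.45) in CD4 cells (4087 UMIs), and Cd8b1 was among the 10 leading genes of the resting-like naive cluster. In the TCRab library 11.1% of cells had Cd4 only, 35.6% Cd8 only, 3.10% both and 50.2% neither. Without thinning the neither class fell to 26.6% in TCRab, 52.7% in CD4 and 0.687% in CD8.

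**Figure D4:**
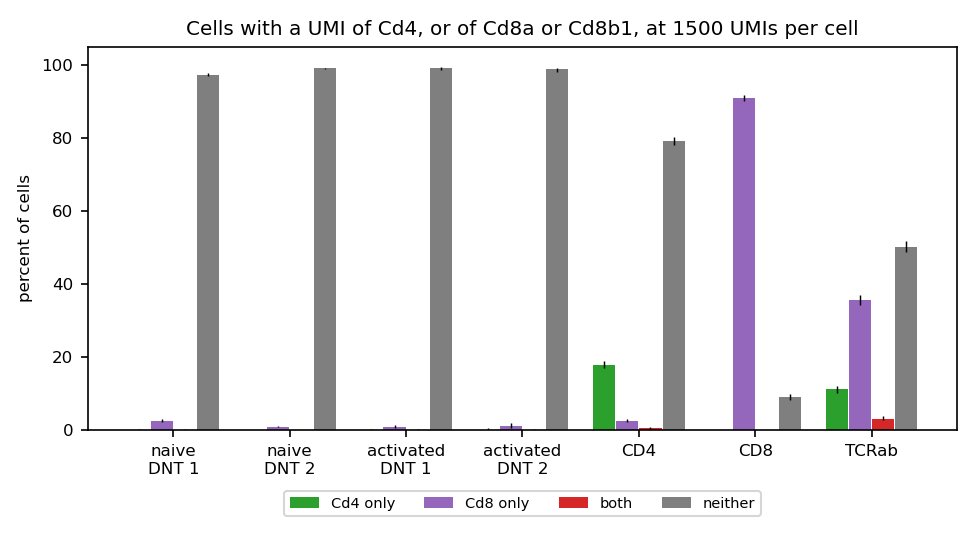
Percent of cells with a UMI of Cd4 only, of Cd8a or Cd8b1 only, of both or of neither, after thinning to 1500 UMIs per cell. Bars are single libraries with exact 95% binomial intervals. The class with neither holds 97.45% of cells in naive DNT replicate 1, 79.2% in CD4, 9.06% in CD8 and 50.2% in TCRab.

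Markers of other cell types varied between libraries. Myeloid marker genes together reached 2072 and 460 CPM in naive DNT replicates 1 and 2, 186 and 353 CPM in activated DNT, 556 CPM in CD4, 218 CPM in CD8 and 691 CPM in TCRab. Of these, S100a8 was at 830 CPM in naive replicate 1 and 22.8 CPM in replicate 2. Red cell genes together were at 3675 and 814 CPM in naive DNT, 0 and 0.434 CPM in activated DNT, 2823 CPM in CD4, 2560 CPM in CD8 and 2140 CPM in TCRab. B cell genes reached 447 CPM over 13 genes in naive replicate 1 and 907 CPM over 15 genes in replicate 2, of which Ighm and Igkc, found in the kit v3 reference only, made up 246 and 100.1 CPM. Cd79a was at 2.25 and 34.6 CPM, and a B cell cluster held 1 and 110 cells. Cells with UMIs of at least 3 plasma cell or platelet genes made up at most 0.0602% and 0.0470% of any library. The NK gene Ncr1 was at no more than 1.14 CPM in any library, and Klrb1c, the gene of the NK1.1 gate, at 13.4 and 12.7 CPM in naive DNT, 0.276 CPM in CD4, 0.912 CPM in CD8 and 0.490 CPM in TCRab.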

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

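Both tests of Trdc were chosen after the result was seen, as were the checks that voided the handling test and the test of captured cells, and the others before. The kit v3 reference alone holds the T cell receptor and immunoglobulin constant genes, so these signals lie outside the comparisons. They were listed because they exceeded the limit that a count of 0 allows. That limit was 0.0559 CPM in naive DNT replicate 2 and 0.118 CPM in activated DNT replicate 2. It shows presence only, since Trav11 passed it with 7 UMIs in activated DNT replicate 2. Whether the levels are unusual for αβ T cells was not tested, because the CD4, CD8 and TCRab libraries used the kit v2 reference. Trdc was at 36.6 and 14.8 CPM in naive and activated DNT replicate 2, Tcrg-C1 at 49.2 and 10.8 CPM, Tcrg-C2 at 71.7 and 43.2 CPM and Tcrg-C4 at 40.2 and 30.3 CPM, in cells sorted as TCRγδ−. Trav11, a segment of invariant NKT receptors, was at 1.55 and 0.276 CPM in cells sorted as CD1d tetramer negative. Igkc, an immunoglobulin gene, was at 100.1 and 7.85 CPM.

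Trdc was at 378 CPM in the Ccr9 and Igfbp4 cluster of naive DNT replicate 2, against 26.9 CPM in the other T clusters together. Free RNA shared by all droplets would give like shares in all clusters, but the share of cells with a Trdc UMI was 10.7 times that of the other T clusters (30% of 260 against 2.79% of 6232 cells at 1500 UMIs). γδ T cells, which the gate excluded, cannot be told apart from αβ cells here, since no γδ cells were measured for reference: Trac in the 77 cells with 3 or more Trdc UMIs was 1.04 times that in the 128 cells with none (bootstrap interval 0.853 to 1.26), Trbc1 and Trbc2 were higher in the first cells than in the second (2001 and 1315 CPM, 3379 and 2510 CPM), and so were Tcrg-C1, Tcrg-C2 and Tcrg-C4 (123 and 76.5 CPM, 246 and 111 CPM, 170 and 80.3 CPM). Another candidate explanation that stays open and untested is that αβ T cells of this cluster transcribe Trdc, whose gene (ENSMUSG00000104876, chromosome 14, 54142851 to 54148868) lies within the Tra locus. The pattern rests on 1 library.

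Immediate early genes were higher in naive DNT than in CD4, CD8 and TCRab cells. Among 9 T clusters of naive replicate 1 the lowest median log2 ratio was 1.10 (highest 2.39). This argues against a subset of DNT cells confined to some clusters as the source. A subset spread over all clusters was not tested, since UMIs were summed per cluster. The median against CD4 was 1.76 without the red cell, myeloid and B cell clusters and 1.74 with all cells. This argues against the cells of those clusters, 71 of 4049, as the source. RNA of non-T cells in the droplets of T cells was not tested. A UMI of a B or myeloid marker gene was found in 47.5% of cells in naive replicate 1. That share was 18.5% in naive replicate 2, 14.1% in TCRab, 10.8% in CD4 and 10.6% in CD8. Handling of the preparation cannot be told apart from biology: myeloid cells found by 3 or more marker genes had a median log2 ratio of 1.46 (1.25 to 1.73), but the test is void because only 59 of the 489 cells found in naive replicate 1 lay in non-T clusters and 76.5% carried Cd3e. The sort gate, which differs between these groups, stays open as a biological explanation.

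Hbb-bs, Hba-a1 and Lyz2 were abundant in the naive DNT libraries and nearly absent from the activated ones. Free RNA in all droplets would give like shares in the T clusters, and the lowest share of cells with an Hbb-bs UMI among 6 T clusters was 0.596 of the highest (31.8% and 53.4%), so it is a candidate source of the UMIs in those clusters. A median of 95.3% of the UMIs of the 3 genes (89.4% to 97.7%) lay in the non-T clusters. Those clusters held 71 of 4049 cells in replicate 1 and 164 of 6728 in replicate 2. Free RNA shared evenly by all droplets would not gather in so few cells. These values therefore argue against it as the source of most of these UMIs. Captured red and myeloid cells, which the CD3+ gate should remove, were not tested by this share, because the clusters were picked by the same genes. That explanation stays open. No biological explanation was tested.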

How the results depend on the processing

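The alternatives that left out the 5% of cells with the highest Scrublet scores, that left out red cell, myeloid and B cell clusters, and that left out a library from the cluster shares were chosen after seeing the data, the others before. Of 76 called named genes between activated and naive cells, 42 kept direction and side of the threshold under all 18 alternatives and 34 lost the call under at least 1, 26 of them with 1 library left out, and no called gene changed direction. The block ended the call of Cd7, brought 15 other named genes past the threshold and changed no list's call by camera. Thinning to 1500 UMIs, which lowers counts and also weights cells equally, ended 25 named calls, and depth limits the Cd4 and Cd8 classes. Except where a cause follows from how an alternative is built, the cause was not tested.

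The number of genes called between activated and naive cells was 1280, and 547 to 2074 with 1 library left out. It was 4894 with the replicate block, 4803 with the block and non-T clusters left out, 2348 with DESeq2 (1269 of the 1280 shared), 2188 with no filter on low counts, 559 when tested against a fold of 2 and 312 with cells thinned to 1500 UMIs (305 shared), where fewer counts remain. With size factors, voom, other barcode filters, doublets or non-T clusters left out, it stayed within 1.5 times. With an estimated correlation 0 of 12 lists were past the camera threshold. Against CD4, CD8 and TCRab the counts were 150, 110 and 99 with a fold of 3, 1127, 1026 and 933 without the CPM minimum, and 77, 62 and 63 with a minimum of 100 CPM, as the stricter or looser rules imply. With 1 naive library left out they were 343 to 2018, 271 to 2101 and 276 to 1937. With non-T clusters left out they were 274, 206 and 221.

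With naive replicate 2 in place of replicate 1, some list medians turned from negative to positive: quiescence 0.47 against CD4, 0.68 against CD8 and 0.42 against TCRab, cholesterol synthesis 0.65, 1.0 and 0.72, and nucleolus and MYC 0.31 against CD8 and 0.38 against TCRab. Kit and replicate change together there, and the ratios of all genes are higher: TMM scaling would shift replicate 2 by −0.68, −0.80 and −0.61 against CD4, CD8 and TCRab, which is more than each of these medians except those of cholesterol synthesis against CD8 and TCRab. With only list members of at least 20 CPM, 9 list medians moved inside the random range: proliferation (−0.06, −0.02 and −0.15) and apoptosis (0.30, 0.38 and 0.18) against CD4, CD8 and TCRab, activation receptors (0.22) and ribosomal proteins (−0.17) against CD4, and cytotoxic genes (0.48) against CD8.

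Cluster classes moved with the settings (means of both libraries in percent). At resolution 0.3 naive cytotoxic-like cells were 60.0, innate-like 10.7 and interferon-responding 5.31. At resolution 1.0 naive innate-like cells were 37.6, activated cytotoxic-like 10.6 and type 1-like 9.11. With 15 principal components naive innate-like cells were 37.1, interferon-responding 2.54 and resting-like 3.94. Without per-library scaling naive cytotoxic-like cells were 28.7 (1.61 and 55.8 in replicates 1 and 2), innate-like 10.8, interferon-responding 1.82 and resting-like 1.83 (0.0247 and 3.63), and activated type 17-like cells were 0.168 and 17.8 in the 2 replicates. With 15 principal components a B cell cluster held 0.0558 and 5.55 of the activated libraries. With Scrublet doublets left out naive innate-like cells were 40.1, activated cytotoxic-like 25.8 and type 1-like 7.72. That setting left out 0 and 1 cells of the naive and 1 and 9 cells of the activated replicates 1 and 2. With so few cells left out, these shifts are not evidence of an effect of doublets. With the highest 5% of Scrublet scores left out naive innate-like cells were 45.3, resting-like 3.07 and activated type 1-like 9.20. With cell cycle genes left out activated type 1-like cells were 10.9. Some classes had no cluster of that name and so no value: naive cycling and red cells with 15 components, naive resting-like cells at resolution 0.3, activated cytotoxic-like cells at 0.3, with 15 components and without the highest Scrublet scores, activated type 1-like cells at 0.3 and without scaling, and activated type 17-like cells at 0.3.

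The share of cells with neither Cd4 nor Cd8 followed depth. With at least 2 UMIs needed it was 77.5% in TCRab, 99.8% in naive DNT, 99.9% in activated DNT, 97.6% in CD4 and 27.5% in CD8, where DNT values are means of both libraries. Without thinning it was 26.6%, 95.6%, 94.6%, 52.7% and 0.687% in the same order. Thinned to 1000 UMIs it was 60.3% in TCRab, 99.4% in activated DNT, 85.5% in CD4 and 18.4% in CD8.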

Other observations

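No test was run for the values below, and their genes and clusters were chosen after the values were seen. Activated DNT cells held an unnamed cluster led by Ccl20, Il22, Il17a, Il2, Il4 and Il13, cytokines of several helper types. It made up 10.1% (8.75 to 11.6) of replicate 1 and 1.48% (0.944 to 2.22) of replicate 2, with medians of 42805 and 40729 UMIs per cell, against 15795 and 9386 in the whole libraries. A cytotoxic-like cluster with Gzma, Gzmk and Ccl5 held 17 cells of replicate 2 (1.10%) and 0 of 1791 cells of replicate 1. Cytotoxic-like clusters held 14.01% of replicate 1 and 7.23% of replicate 2 at resolution 1.0. They held 33.2% and 18.4% when the 1 and 9 cells that Scrublet called doublets were left out.

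Naive DNT cells also held an unnamed cluster led by Ly6a, Il4, Cxcr6 and Id2, with 1.80% (1.42 to 2.26) of replicate 1 and 4.06% (3.599 to 4.56) of replicate 2. Zbtb16 was at 3.80 and 23.97 CPM in the naive libraries and 0.230 CPM in CD4. Foxp3, the factor of regulatory T cells, was at 9.88 CPM in CD4 and 6.97 CPM in TCRab, against 0.230 and 0.876 CPM in naive DNT. In the TCRab library the 132 cells with both Cd4 and Cd8 UMIs had a median of 3653.5 UMIs, against 3816.5 in cells with Cd4 only and 4356 in cells with Cd8 only.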
